A study of Arabidopsis thaliana with 12 samples.

How the data were processed

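Poly(A) RNA was measured in 12 leaf samples of Arabidopsis thaliana, 3 from each of 4 genotypes. Leaves of 4-week-old plants had been syringe-infiltrated with Pst AvrRps4, a Pseudomonas syringae pv. tomato strain that delivers the effector AvrRps4, at an OD600 of 0.005. The tissue was taken 4 h later, and each library came from a pool of 4 plants. Per the labels, the genotypes were Col-0, the mutant eds1-2, a line called w.tEDS1 that carries wild-type EDS1, and a line that carries the EDS1 variant R493A. The labels give neither the background of the last 2 nor the number of independent lines. Mock-treated and untreated samples were not used here, so no comparison measures the response to infection itself. Per the labels' protocols, RNA was purified with an RNeasy kit and libraries were made with the TruSeq v2 kit, which does not mark strand.

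The deposited table holds raw read counts per gene for each library, made by the authors on genome build TAIR 10. The submitters' processing notes name TopHat2, HTSeq and limma without versions, roles or settings. The table has 32678 genes and 5 summary entries that name no gene, which took 9.69% to 22.9% of a library's column total and were left out. The genes' counts summed to between 19273912 and 24572145 per library. A gene without a count in the 3 Col-0 libraries could still lie at up to 3 counts over the group, which is 0.0465 CPM, the unit of read counts scaled to a common library total. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Reads that mapped to more than 1 place were set aside in a summary entry, so genes with near-identical copies, such as EDS1 and its neighbour EDS1B, have uncertain counts. The counting did not state a strand setting, so reads of overlapping and antisense genes cannot be told apart.

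Groups were taken from the labels, and all 12 columns matched a sample. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 18770, and library sizes were scaled by the TMM method. A quasi-likelihood model with the genotype as its only term was fitted to all 12 libraries, and each of 6 pairs of groups was compared with glmQLFTest. The difference between the R493A effect, taken against w.tEDS1, and the eds1-2 effect, taken against Col-0, was tested in the same model. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes with an adjusted p under 0.05 are called higher or lower. Every adjusted p of a gene comes from this edgeR test unless another tool is named. Fold changes are on the log2 scale with a prior count of 0.125. Levels are TMM-scaled CPM with the SD over 3 libraries. Intervals of fold changes are at 95%, from the edgeR fit, and include the spread between libraries.

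The tests, the named genes, the gene lists and most alternatives were fixed before the data were examined. Named genes are EDS1, EDS1B, PR1, ICS1, PAD4, FMO1, MYC2 and VSP2 in each comparison. To them were added, from called genes of at least 5 CPM on average whose groups do not overlap, the 6 largest increases and the 6 largest decreases, and up to 3 called members of each list with the lowest adjusted p. Genes outside this rule are named as chosen after their values were seen. The 17 lists hold 267 genes, of which 257 were tested. They cover the EDS1 module with its helper receptors, salicylic acid and pipecolic acid metabolism, salicylic acid response, jasmonate, pattern-triggered immunity, camalexin and indole glucosinolates, ethylene, abscisic acid, auxin, photosynthesis, the circadian clock, touch and rapid stress, heat shock and senescence. The remaining 3 are markers of guard cells, phloem and dividing cells. The EDS1 module list holds EDS1 and EDS1B themselves, so its tests include the gene that the lines differ in. Each list was tested in each comparison with limma 3.58.1 camera on voom values, with a preset inter-gene correlation of 0.01 and again with an estimated one. Limma's fry, a rotation test of a shared direction, was planned beside camera, and the lists it called are given for each comparison. These p-values were adjusted over the 17 lists of a comparison. The calls within 2 Mb of EDS1 were compared with the rest of the genome by Fisher's exact test. Gene symbols and coordinates come from the TAIR10.1 RefSeq annotation, which matched 31912 of the 32678 identifiers.

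The alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, the sequencing run as a covariate, libraries of the main sequencing run alone, the 6 libraries compared alone, each library left out in turn, other window sizes and a minimum change of 1 on the log2 scale. After the data were examined, voom with quality weights, 1 surrogate variable from sva 3.50.0, the replicate block within 6 libraries, the sequencing lane as a covariate and lane 7 of the main run alone were added. With the lane as a covariate Col-0 rests on replicate 3 alone, eds1-2 on replicates 2 and 3 and R493A on replicates 1 and 3, since the others lay in lanes of 1 genotype. Lane 7 holds the 3 w.tEDS1 libraries, which alone supply the spread there, and 1 library of each other genotype. Lone libraries are assumed to vary like the other groups. The fits by lane leave 4 and 2 residual degrees of freedom, and other ranges over settings are given without them. The labels give every group replicates 1 to 3 without saying what a number marks. Deviations from the group means correlated within same-numbered R493A and w.tEDS1 libraries at 0.105, 0.381 and 0.139. All 3 exceed 0.1, so the paired fit is printed beside that comparison. In no other comparison did all same-numbered libraries deviate together. The procedure was tested on counts simulated for R493A against w.tEDS1 over 18619 genes. It called 86% of genes changed 4-fold, 42% of genes changed 2-fold and 5 unchanged genes. The simulation drew each gene independently, without the variation that genes share within a group. These shares therefore may not hold for the real libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.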

Results

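Gene expression was compared between 4 genotypes of Arabidopsis leaves, each with 3 libraries, 4 h after infiltration with Pst AvrRps4. AvrRps4 is recognised by the paired receptors RPS4 and RRS1, and EDS1 encodes the lipase-like regulator through which such TIR-type receptors act. The series was designed around eds1-2, which lacks EDS1 function, and R493A, an exchange of arginine for alanine in EDS1, with Col-0 and w.tEDS1 as lines with wild-type EDS1. The sum of gene counts per library ranged from 19760162 to 23677078 in Col-0, from 20472553 to 22133552 in w.tEDS1, from 21884984 to 24572145 in eds1-2 and from 19273912 to 22694032 in R493A. Libraries eds1-2 replicate 1 and R493A replicate 2 came from 1 sequencing run and the other 10 from another, the main run, where Col-0 replicates 1 and 2 shared lane 6 with no other library. The Col-0 libraries stood furthest apart from one another. On the first principal component of log2 CPM, with 41.7% of the variance, Col-0 replicates 1 and 2 lay at −62.9 and −92.6, Col-0 replicate 3 at −0.307 and the other libraries between −1.68 and 48.5. The median SD of log2 CPM across genes was 0.254 in Col-0, against 0.163 in w.tEDS1, 0.185 in eds1-2 and 0.156 in R493A. PAD4, a partner of EDS1, lay at 48.6, 302 and 27.2 CPM in Col-0 replicates 1, 2 and 3, and ICS1, the main enzyme of pathogen-induced salicylic acid synthesis, at 42.1, 279 and 17.7 CPM.

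EDS1 (AT3G48090, chromosome 3, 17755329 to 17758147 in TAIR10.1) was lowest in the 3 eds1-2 libraries and highest in the 3 w.tEDS1 libraries. Its level was 42.5 ± 25.9 CPM in Col-0 (SD, n = 3), 144 ± 45.9 in w.tEDS1, 3.94 ± 0.141 in eds1-2 and 24.7 ± 5.96 in R493A. EDS1 was lower in eds1-2 than in Col-0 by the edgeR quasi-likelihood test (log2 fold change −3.43, SE 0.41, adjusted p = 0.00171) and higher in w.tEDS1 than in eds1-2 (5.19, SE 0.44, adjusted p = 0.00185). It was lower in R493A than in w.tEDS1 (−2.54, SE 0.38, adjusted p = 0.0256). R493A stood 2.65 above eds1-2 on the log2 scale (95% interval 1.72 to 3.57, adjusted p = 0.0570) and 0.78 below Col-0 (log2 fold change −0.78, interval −1.62 to 0.06, adjusted p = 0.265), and neither difference passed the threshold. Against Col-0, EDS1 in R493A lay at −0.18 without Col-0 replicate 2 and at −1.08 without Col-0 replicate 3. EDS1B (AT3G48080, 17752463 to 17755190), its neighbour and near-identical copy, lay at 9.99 ± 7.65 CPM in Col-0, 2.01 ± 0.745 in w.tEDS1, 0.280 ± 0.197 in eds1-2 and 0.367 ± 0.189 in R493A, with reads that the 2 genes may share. The call between eds1-2 and Col-0 was lost against Col-0 replicate 3 alone, with the lane in the model (−2.32, SE 0.57, adjusted p = 0.999) and in lane 7 alone (−2.51, SE 0.46, adjusted p = 0.683). The call for w.tEDS1 against eds1-2 was lost in the main run alone (adjusted p = 0.109), with the lane in the model (4.95, SE 0.54, adjusted p = 0.255) and in lane 7 alone (5.15, SE 0.48, adjusted p = 0.246). The call between R493A and w.tEDS1 was lost when any library but w.tEDS1 replicate 1 was left out (adjusted p up to 0.175) with the run as a covariate or in the main run alone (up to 0.207), and with the lane (−2.33, SE 0.46, adjusted p = 0.295) or in lane 7 alone (−2.22, SE 0.38, adjusted p = 0.524).

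The comparison of eds1-2 with Col-0 asks what the leaf lacks without EDS1, and differences that w.tEDS1 shares do not answer it. WRKY70 (AT3G56400), a transcription factor induced by salicylic acid, fell from 291 ± 92.3 CPM in Col-0 to 22.3 ± 5.99 in eds1-2 (log2 fold change −3.70, SE 0.35, adjusted p = 0.000338; edgeR, n = 3). Its close relative WRKY54 (AT2G40750) fell from 109 ± 44.3 to 10.3 ± 2.38 CPM (−3.41, SE 0.37, adjusted p = 0.000932). SARD1 (AT1G73805), an activator of ICS1 transcription, fell from 123 ± 76.4 to 10.6 ± 0.82 CPM (−3.54, SE 0.44, adjusted p = 0.00218). The ribulose bisphosphate carboxylase subunit gene RBCS1B (AT5G38430) was higher in eds1-2, at 442 ± 40.8 against 259 ± 37.8 CPM (0.77, SE 0.13, adjusted p = 0.0197).

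Of the 13 genes of salicylic acid and pipecolic acid metabolism, 9 fell and 12 were called lower when p-values were adjusted over the list alone, with a median of −2.70. Among them were UGT76B1 (−2.70, adjusted p = 0.00654), PBS3, which makes a salicylic acid precursor (−3.66, adjusted p = 0.0148), ICS1 (−3.81, adjusted p = 0.0416) and FMO1, which makes N-hydroxypipecolic acid (−4.82, adjusted p = 0.0408). Of 21 salicylic acid response genes, 13 fell and 19 were called lower when adjusted over the list alone, with a median of −3.11, and they included WRKY51 (−5.57, adjusted p = 0.00107). PR1, the usual marker of this response, lay at 0.0639 CPM in eds1-2 and at 8.90 ± 12.9 CPM in Col-0, a difference that did not pass (−7.13, SE 2.62, adjusted p = 0.144). In the EDS1 module, 5 of 14 genes fell and 9 were called lower when adjusted over the list alone. They included PAD4 (−3.38, adjusted p = 0.0422) and the helper receptor NRG1.2 (−1.45, adjusted p = 0.0364). The median was −0.77. With camera the 3 lists were lower (adjusted p = 3.18e-09, 4.00e-15 and 2.12e-07). With an estimated correlation none of the 3 passed (adjusted p = 0.223, 0.223 and 0.359). Fry called the 3 lower (adjusted p = 0.00794, 0.00794 and 0.0381) and no other list of this comparison.

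Medians of further defence lists in eds1-2 were −0.79 for 23 genes of pattern-triggered immunity, of which MKK4 (−1.15, adjusted p = 0.0472) and SOBIR1 (−0.79, adjusted p = 0.0427) were called, and −0.74 for 18 camalexin and indole glucosinolate genes, of which MYB51 (−2.30, adjusted p = 0.0418) and CYP71A12 (−3.98, adjusted p = 0.0497) were called. They were −0.90 for 12 ethylene genes, of which EBF2 (−0.98, adjusted p = 0.0408) was called, and −1.01 for 9 senescence genes. Adjusted over the list alone, the counts lower were 4, 6, 4 and 4. With camera these lists were lower (adjusted p = 2.57e-05, 0.000347, 0.000819 and 0.00169), and with an estimated correlation none was (adjusted p = 0.422, 0.359, 0.381 and 0.359). All 25 photosynthesis genes had positive values, with a median of 0.36 (camera adjusted p = 1.00e-08, adjusted p = 0.359 with an estimated correlation), and 1 was called. The 7 guard cell markers had a median of 0.58 (camera adjusted p = 0.00990, adjusted p = 0.381 with an estimated correlation). In w.tEDS1, which carries wild-type EDS1, these lists moved the same way against Col-0. Their medians there, in the same order, were −0.64, −0.66, −0.82, −1.23, 0.40 and 0.37. The shifts against Col-0 were therefore not particular to eds1-2. The jasmonate list was not called (median −0.18, camera adjusted p = 0.156), with MYC2, a central jasmonate regulator, at 0.00 (adjusted p = 0.999) and VSP2 at 0.95 (adjusted p = 0.101). Of its 30 tested members 4 had an unadjusted p under 0.05, and edgeR, DESeq2 and limma-voom called 0. Nor were the lists for abscisic acid (median −0.18, camera adjusted p = 0.449), auxin (−0.14, adjusted p = 0.697), touch and rapid stress (−0.49, adjusted p = 0.0664), heat shock (−0.41, adjusted p = 0.306), phloem (0.11, adjusted p = 0.346), dividing cells (0.31, adjusted p = 0.179) and the circadian clock (0.15, adjusted p = 0.313), in which RVE1 was called higher (1.2, adjusted p = 0.0472).

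In all, 113 genes were higher and 270 lower in eds1-2 than in Col-0, and 260 of the 383 changed by at least 1 on the log2 scale. Without Col-0 replicate 3 the count was 3338, including all 383, and without Col-0 replicate 1 or 2 it was 97 or 130. Without eds1-2 replicate 1, 2 or 3 it was 57, 67 or 90. WRKY70, WRKY54, WRKY51 and SARD1 stayed called without any single library and in the 10 other settings without the lane (adjusted p up to 0.0422). UGT76B1 was lost without eds1-2 replicate 1 (adjusted p = 0.0541, up to 0.0565 over the settings without the lane), and PBS3 without any eds1-2 library (up to 0.161). ICS1 and PAD4 were lost without Col-0 replicate 1 or any eds1-2 library (up to 0.227). Without Col-0 replicate 2 the values moved to −1.90 for ICS1, −1.65 for PAD4, −2.84 for FMO1, −1.39 for MYB51 and −2.62 for CYP71A12. PR1 moved to −4.56 without Col-0 replicate 1. The call of RBCS1B was lost without any library but Col-0 replicate 3 and eds1-2 replicate 3 (up to 0.198). FMO1, NRG1.2, MYB51, CYP71A12, MKK4, SOBIR1, EBF2 and RVE1 were lost without any library but Col-0 replicate 3 (adjusted p up to 0.273 over the settings without the lane). With the lane in the model 13 genes were called and in lane 7 alone 10, with 4 and 2 residual degrees of freedom and Col-0 replicate 3 as the only library for Col-0 in both. Of 31 named genes called, 8 and 7 then kept their calls, each on chromosome 3 (adjusted p of the others up to 1 and 0.996), and all 31 kept their direction. WRKY70 lay at −2.75 (SE 0.42, adjusted p = 0.182) and −2.77 (SE 0.52, adjusted p = 0.683).

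**Figure D1:**
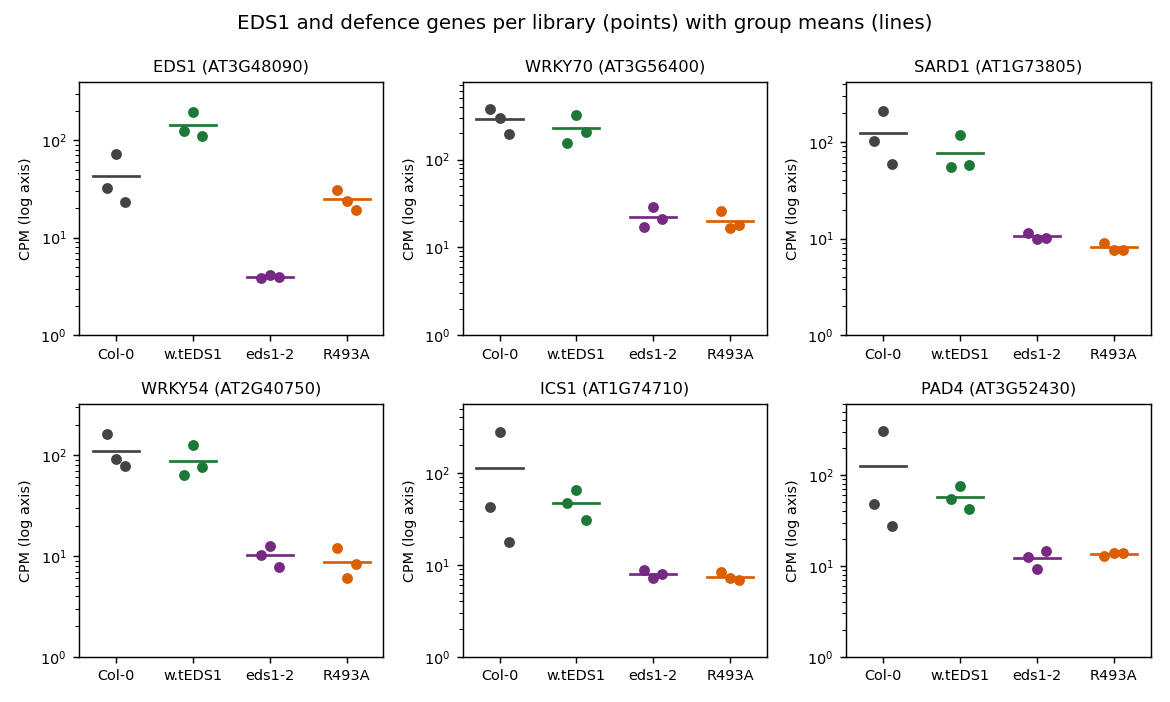
Normalised read counts (CPM, log axis) of EDS1 and 5 defence genes in each of the 12 libraries, with points for libraries and lines for the means of the 4 genotypes. WRKY70 lies at 291 CPM in Col-0 and 227 CPM in w.tEDS1 on average, against 22.3 CPM in eds1-2 and 20.2 CPM in R493A, while PAD4 and ICS1 spread widely among the Col-0 libraries.

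A block of chromosome 3 around EDS1 differed between Col-0 and each of the other 3 lines. HR4 (AT3G50480), a homolog of the RPW8 resistance genes, lay at 1030 ± 545 CPM in Col-0 (SD, n = 3), 0.641 ± 0.128 in eds1-2 and 1.63 ± 0.863 in w.tEDS1 (edgeR log2 fold change against Col-0 −10.66, adjusted p = 4.11e-06, and −9.29, adjusted p = 8.13e-06). The receptor-like kinase gene CRK4 (AT3G45860) had 0 counts in eds1-2 against 1616 in Col-0, at least 580-fold lower, and 0 in R493A, and its call in eds1-2 was lost in the 6 libraries alone (adjusted p = 0.0646). AT3G47680 likewise had 0 counts in eds1-2 against 1331 in Col-0, at least 480-fold lower. AT3G44430 had 1 count in eds1-2 and AT3G43740, a leucine-rich repeat gene, had 2, against 1779 and 1362 in Col-0. Higher in eds1-2 were FAR8 (AT3G44560), a fatty acid reductase gene, at 49.5 ± 4.66 against 0.506 ± 0.157 CPM (6.62, SE 0.29, adjusted p = 1.49e-06), the glycosyl hydrolase gene AT3G44070, with 1275 counts against 2, and the lectin kinase gene AT3G45440 (4.80, adjusted p = 1.15e-05). The retrotransposon SADHU3-2, on the same chromosome (6.24, adjusted p = 0.000364), GSA2, a gene of tetrapyrrole synthesis (1.51, adjusted p = 0.000377), and the receptor kinase gene AT3G47580 (1.58, adjusted p = 0.000307) were higher too. SADHU3-2 had 8 counts in Col-0, all in replicate 2, so the size of its fold is unknown without that library. The U-box gene PUB54 on chromosome 1 fell (−6.11, adjusted p = 0.0173, lost without any eds1-2 library, up to 0.172 over the settings without the lane), and so did EDS1B (−5.16, adjusted p = 0.0186, lost without Col-0 replicate 1 or any eds1-2 library, up to 0.161). PUB54 lay at −4.09 without Col-0 replicate 2 and at −6.63 without Col-0 replicate 3.

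Within 2 Mb of EDS1, 86 of 646 tested genes were called between eds1-2 and Col-0, or 13.3%, against 1.64% elsewhere (odds ratio 9.22, 12 higher and 74 lower). The window held 68 of the genes called between w.tEDS1 and Col-0 (10.5% against 0.75%, odds ratio 15.6) and 81 of those called between R493A and Col-0 (12.5% against 1.39%, odds ratio 10.2). Fisher's exact test gave adjusted p = 2.22e-45, 1.19e-47 and 2.22e-45 over the 6 comparisons. Between the 3 lines other than Col-0 the window held 1, 2 and 0 called genes, without enrichment (adjusted p = 0.582, 0.787 and 1). The 0 calls between R493A and eds1-2 by edgeR stand beside genome-wide counts of 404 at an unadjusted p under 0.05, 31 called by DESeq2 and 7 by limma-voom. In bins of 1 Mb, the enrichment lay between 15 and 19 Mb in all 3 comparisons with Col-0, at 22.6% of 164 genes in the bin from 17 Mb in eds1-2. A bin at 12 Mb of chromosome 1 held 8 of 101 genes called in eds1-2 (adjusted p = 0.0248). A read from another haplotype that maps poorly to the Col-0 reference would lower a count in the same way as a lower transcript level. Without the window, 297, 136 and 252 genes were called in the 3 comparisons with Col-0.

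**Figure D2:**
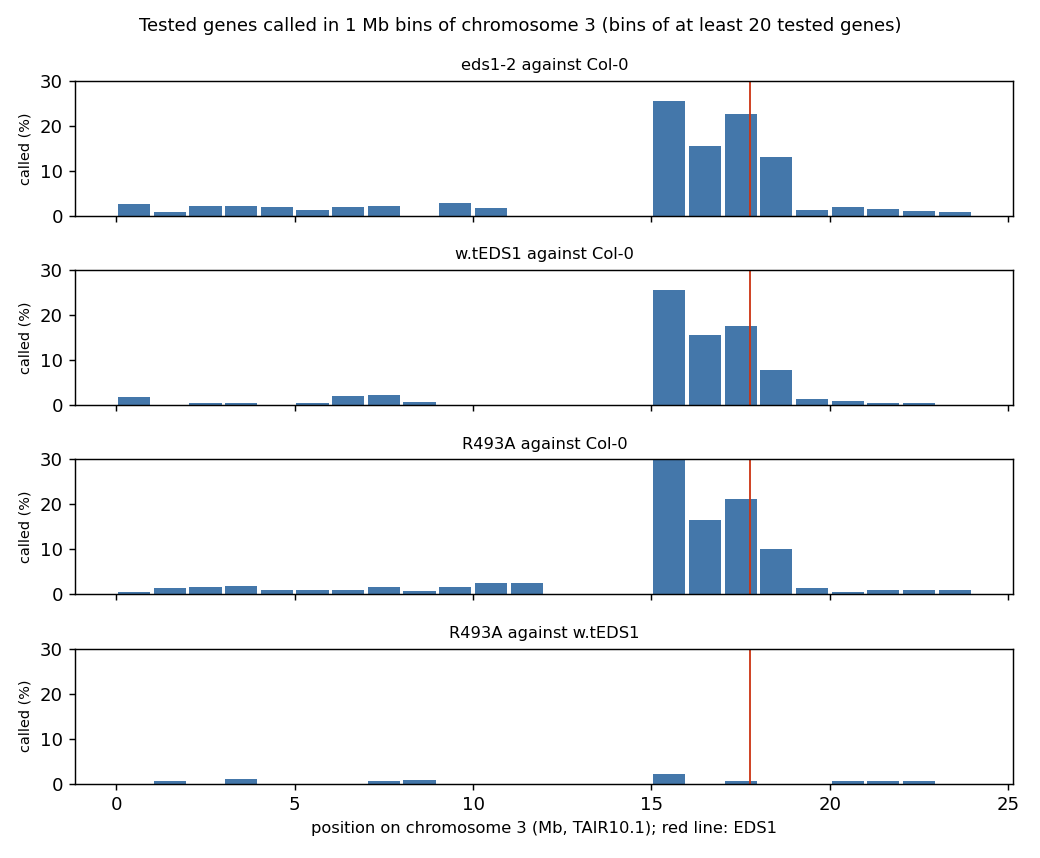
Share of tested genes called (%, bars) in bins of 1 Mb along chromosome 3 (Mb, TAIR10.1) in 4 comparisons, with a red line at EDS1. The bars rise between 15 and 19 Mb in the 3 comparisons with Col-0, to 22.6% at 17 Mb in eds1-2, and not in R493A against w.tEDS1.

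The comparison of w.tEDS1 with eds1-2 asks what wild-type EDS1 brings to the leaf. Next to EDS1 itself, 13 genes were higher in w.tEDS1, of which 5 are in the lists of salicylic acid metabolism and response. WRKY70 lay at 227 ± 87.0 CPM in w.tEDS1 and 22.3 ± 5.99 in eds1-2 (log2 fold change 3.34, SE 0.34, adjusted p = 0.00742; edgeR, n = 3), and WRKY54 at 88.2 ± 32.2 against 10.3 ± 2.38 CPM (3.1, SE 0.37, adjusted p = 0.0194). SARD1 (2.88, SE 0.43, adjusted p = 0.0368) and WRKY51 (4.91, SE 0.63, adjusted p = 0.0249) were also higher. The lectin gene AT5G03350 rose from 7.47 ± 2.01 to 187 ± 145 CPM (4.64, SE 0.68, adjusted p = 0.0368), and AT3G22235, which encodes a small cysteine-rich membrane protein, from 9.58 ± 2.61 to 108 ± 33.7 CPM (3.5, adjusted p = 0.0338).

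The other named genes called higher were AT1G19960 (3.57, adjusted p = 0.0265), the hydrolase gene AT5G24200 (3.61, adjusted p = 0.0368) and AT5G55450, a lipid-transfer protein gene (3.49, adjusted p = 0.0368). The remaining 4 genes, NIMIN1, AT2G41090, AT1G72910 and AT5G26690, are named after their values were seen, with log2 fold changes of 5.87, 1.95, 2.51 and 5.95. ICS1 (2.56), PAD4 (2.26), FMO1 (2.55), PR1 (7.16), EDS1B (2.85), MYC2 (−0.21) and VSP2 (−0.79) did not pass, with PR1 at 2.97 without w.tEDS1 replicate 3. Of 21 salicylic acid response genes all had positive values, 4 were called and 16 when adjusted over the list alone (median 2.27, camera adjusted p = 1.53e-43, adjusted p = 0.0301 with an estimated correlation). Of 13 metabolism genes 1 was called and 6 when adjusted over the list alone (median 1.73, camera adjusted p = 2.20e-16, adjusted p = 0.0470 with an estimated correlation). In the EDS1 module 1 of 14 was called, EDS1, and 5 when adjusted over the list alone (median 0.43, camera adjusted p = 7.80e-16, adjusted p = 0.0805 with an estimated correlation). The mean of that list, which holds EDS1 and EDS1B, was 1.11. The jasmonate list was lower in w.tEDS1 (median −0.28, 29 of 30 negative, camera adjusted p = 2.06e-08, adjusted p = 0.163 with an estimated correlation). So were the lists for abscisic acid (−0.29, camera adjusted p = 0.0141, adjusted p = 0.924 with an estimated correlation) and senescence (−0.28, camera adjusted p = 0.00744, adjusted p = 0.450 with an estimated correlation). Of the jasmonate genes 3 had an unadjusted p under 0.05, and edgeR, DESeq2 and limma-voom called 0. Camera did not call the lists for pattern-triggered immunity (median −0.02), camalexin (0.04), ethylene (0.04), photosynthesis (0.02) and guard cells (−0.2). Their camera adjusted p ranged from 0.431 to 0.666. Fry called only the salicylic acid response list in this comparison, as higher in w.tEDS1 (adjusted p = 0.0343).

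In this comparison 14 genes were called higher and 0 lower, with 499 at an unadjusted p under 0.05, and DESeq2 and limma-voom each called 1 lower. Without w.tEDS1 replicate 2 or 3 the counts were 5 and 4, without eds1-2 replicate 1, 2 or 3 they were 1, 2 and 1, and in the main run alone 0 passed, with 608 at an unadjusted p under 0.05. WRKY70 was lost without eds1-2 replicate 1 or 3 (adjusted p up to 0.168 over the settings without the lane) and WRKY54 without any eds1-2 library (up to 0.243). WRKY51 was lost without those or w.tEDS1 replicate 3 (up to 0.385). SARD1, AT5G03350, AT3G22235, AT1G19960, AT5G24200 and AT5G55450 were lost without any library but w.tEDS1 replicate 1 (up to 0.367). With the lane in the model and in lane 7 alone edgeR called 0 genes, with 660 and 670 at an unadjusted p under 0.05, and lane 7 holds 1 eds1-2 library. There WRKY70 lay at 2.96 (SE 0.38, adjusted p = 0.337) and 2.99 (SE 0.48, adjusted p = 0.610), and all 10 named genes called kept their direction (adjusted p up to 1).

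The comparison of R493A with w.tEDS1 asks what the R493A exchange changes. WRKY70 fell from 227 ± 87.0 to 20.2 ± 4.85 CPM (log2 fold change −3.49, SE 0.35, adjusted p = 0.00260; edgeR, n = 3), WRKY54 from 88.2 ± 32.2 to 8.76 ± 2.96 CPM (−3.33, SE 0.37, adjusted p = 0.00658) and SARD1 from 77.7 ± 36.0 to 8.13 ± 0.818 CPM (−3.25, SE 0.44, adjusted p = 0.0154). WRKY51 (−5.66, SE 0.68, adjusted p = 0.00933), NRG1.2 (−1.89, SE 0.30, adjusted p = 0.0311) and the receptor-like protein gene RLP34 (−3.58, SE 0.56, adjusted p = 0.0305) fell as well. AT5G03350 (−4.77, SE 0.69, adjusted p = 0.0237) and AT5G24200 (−4.09, SE 0.54, adjusted p = 0.0154) were also lower.

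A second set of genes differed here that had not been called between w.tEDS1 and eds1-2. The pseudogene AT4G16870 lay at 2.25 ± 0.807 CPM in R493A and 67.4 ± 13.8 in w.tEDS1 (−4.89, SE 0.33, adjusted p = 0.000151). AT1G54410, a dehydrin gene, lay at 18.6, 0.690 and 0.260 CPM in R493A replicates 1, 2 and 3 and at 1020 ± 57.5 in w.tEDS1 (−7.27, SE 1.16, adjusted p = 0.0311). AT1G57650 had 1 count in R493A and 397 in w.tEDS1. Higher in R493A were AT5G24240, which encodes a phosphatidylinositol 4-kinase gamma-like protein, at 30.5 ± 3.99 against 0.418 ± 0.140 CPM (6.17, SE 0.49, adjusted p = 0.000521), and MAF5, a MADS-box gene related to the flowering repressor FLC, at 15.9 ± 3.13 against 0.921 ± 0.603 CPM (4.09, SE 0.47, adjusted p = 0.00749). The third gene called higher, AT1G54420, named after its values were seen, lay at 3.22 ± 0.564 CPM in R493A and had no read in the other libraries (adjusted p = 0.0256).

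All 21 salicylic acid response genes had negative values, 4 were called and 14 when adjusted over the list alone (median −2.28, camera adjusted p = 2.10e-29, adjusted p = 0.0879 with an estimated correlation). Of the 13 metabolism genes 1 was called, SARD1, and 7 when adjusted over the list alone (median −1.62, camera adjusted p = 6.08e-12, adjusted p = 0.111 with an estimated correlation). In the EDS1 module 2 were called and 6 when adjusted over the list alone (median −0.51, camera adjusted p = 4.90e-09, adjusted p = 0.208 with an estimated correlation). ICS1 (−2.67, adjusted p = 0.496), PAD4 (−2.09, adjusted p = 0.691), FMO1 (−2.66, adjusted p = 0.946), PR1 (−4.32, adjusted p = 0.999) and EDS1B (−2.42, adjusted p = 0.786) did not pass. The value of PR1 rested on w.tEDS1 replicate 3, at 26.35 CPM against 0.24 and 0.74 in the other 2, and was −0.14 without it. Without R493A replicate 2 no PR1 count was left in R493A, so the size of the fold is unknown. The jasmonate list was higher in R493A, with 28 of 30 values positive and a median of 0.39 (camera adjusted p = 2.13e-09, adjusted p = 0.165 with an estimated correlation). Of its genes 6 had an unadjusted p under 0.05, and edgeR, DESeq2 and limma-voom called 0, with VSP2 at 1.01 (adjusted p = 0.491) and MYC2 at 0.48 (adjusted p = 0.999). VSP2 was 0.63 without R493A replicate 2 and 1.28 without R493A replicate 1. The abscisic acid list was higher (median 0.33, camera adjusted p = 0.00194, adjusted p = 0.763 with an estimated correlation). The photosynthesis list was lower (median −0.18, camera adjusted p = 0.000189, adjusted p = 0.763 with an estimated correlation). Fry called only the salicylic acid response list in this comparison, as lower in R493A (adjusted p = 0.0343). Against Col-0 the jasmonate list was lower in w.tEDS1 (median −0.50, camera adjusted p = 3.30e-05) and not called in R493A (−0.10, camera adjusted p = 0.584). Nor was it called in R493A against eds1-2 (0.14, camera adjusted p = 0.259). Its difference from w.tEDS1 therefore cannot be assigned to R493A.

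Between R493A and w.tEDS1, 3 genes were called higher and 39 lower. With the replicate number as a block the count was 15 in the model of 12 libraries, and in a paired fit of the 6 libraries it was 186, with 23 higher and 163 lower, including 35 of the 42. The block ended the calls of NRG1.2, RLP34, AT5G03350 and AT1G54410 in the model of 12 libraries (adjusted p up to 0.241 over the settings without the lane) and ended no list's call. In the main run alone 8 were called. Without w.tEDS1 replicate 2 or 3 the counts were 18 and 14, and without R493A replicate 1, 2 or 3 they were 7, 10 and 4. WRKY70, AT4G16870, AT1G57650 and AT5G24240 stayed called without any single library and in the 11 other settings without the lane (adjusted p up to 0.0397). MAF5 and WRKY54 were lost without R493A replicate 3 (0.0562 and 0.0702), and SARD1, WRKY51 and AT5G24200 without any R493A library (up to 0.156). AT5G03350 and NRG1.2 were lost without those or w.tEDS1 replicate 3, RLP34 without any library but w.tEDS1 replicate 1, and AT1G54410 without any library but R493A replicate 1, without which it lay at −11.03. With the lane in the model 5 genes were called, AT4G16870, AT1G57650 and AT5G24240 among them, and in lane 7 alone, where R493A has replicate 1 only, 2, AT1G54410 and AT5G24240. There WRKY70 lay at −3.15 in both (SE 0.38, adjusted p = 0.130 and SE 0.48, adjusted p = 0.405), and all 14 named genes called kept their direction (adjusted p up to 0.695).

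**Figure D3:**
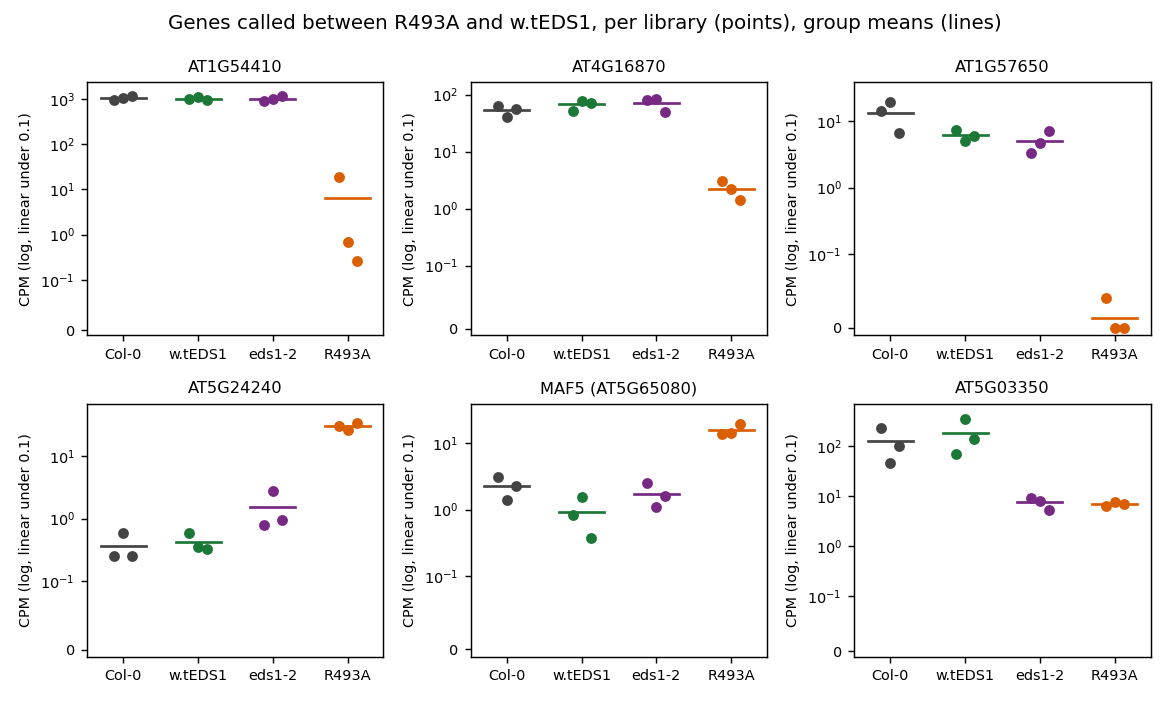
Normalised read counts (CPM, log axis, linear under 0.1) of 6 genes called between R493A and w.tEDS1 in each library, with points for libraries and lines for group means. AT1G54410, AT4G16870 and AT1G57650 are low in R493A and AT5G24240 and MAF5 high in it, apart from the other 3 genotypes, while AT5G03350 is low in both R493A and eds1-2.

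R493A and eds1-2 were compared to ask whether the variant retains part of what the mutant lacks. WRKY70 differed by −0.15 on the log2 scale (95% interval −0.88 to 0.59), WRKY54 by −0.23 (−1.04 to 0.58) and SARD1 by −0.38 (−1.33 to 0.58), each with adjusted p = 1 by edgeR. These 3 genes had been called between w.tEDS1 and eds1-2, with the same eds1-2 libraries, and do not stand for uncalled genes. Their intervals exclude the gain of w.tEDS1 over eds1-2, which was 3.34 (SE 0.34), 3.1 (SE 0.37) and 2.88 (SE 0.43). The 7 genes called were AT4G16870 (−4.98, SE 0.33, adjusted p = 0.000129), AT1G57650 (1 count against 347), AT3G05410, a gene of the PsbP family (−1.85, SE 0.26, adjusted p = 0.0426), AT5G24240 (4.33, SE 0.43, adjusted p = 0.00316), MAF5 (3.19, SE 0.44, adjusted p = 0.0426) and, named after their values were seen, FLC and AGL62, both lower in R493A with adjusted p = 0.0426.

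None of the 14 genes higher in w.tEDS1 than in eds1-2 was called between R493A and eds1-2, where 404 genes had an unadjusted p under 0.05 and DESeq2 and limma-voom called 31 and 7. All 14 were among the 39 genes lower in R493A than in w.tEDS1. Independent lists of these sizes would share 0.0291 genes, but part of the excess may come from the shared w.tEDS1 libraries. At an unadjusted p under 0.05, 65.1% of the genes higher in w.tEDS1 were lower in R493A, against 3.38% for independent lists and 19% on average in 20 simulations of unchanged groups. The simulations drew each gene independently. In the data 1 axis held 43.9% of the variance within groups, so the overlap from shared libraries may be larger than simulated. Of the lists, the photosynthesis genes were lower in R493A (median −0.14, camera adjusted p = 0.000648, adjusted p = 0.926 with an estimated correlation), and the salicylic acid response list was not called (median −0.05, mean 0.25, camera direction lower, adjusted p = 0.922). Fry called no list between R493A and eds1-2. ICS1 (−0.11), PAD4 (0.16), FMO1 (−0.11), PR1 (2.84), EDS1B (0.43), MYC2 (0.27) and VSP2 (0.22) did not pass. With single libraries left out 3 to 5 genes were called, with 3 without eds1-2 replicate 1, 2 or 3 or R493A replicate 3, and 4 without R493A replicate 1. AT4G16870 and AT5G24240 stayed called in every setting without the lane (adjusted p up to 0.0431), AT1G57650 was lost with limma-voom (adjusted p = 0.0844), MAF5 without any single library and AT3G05410 without any but R493A replicate 2 (up to 0.263). Once the lane was modelled 3 genes were called, AT4G16870 and AT1G57650 among them, and in lane 7 alone, with 1 library against 1 and the spread of w.tEDS1, 1, none of the 7.

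**Figure D4:**
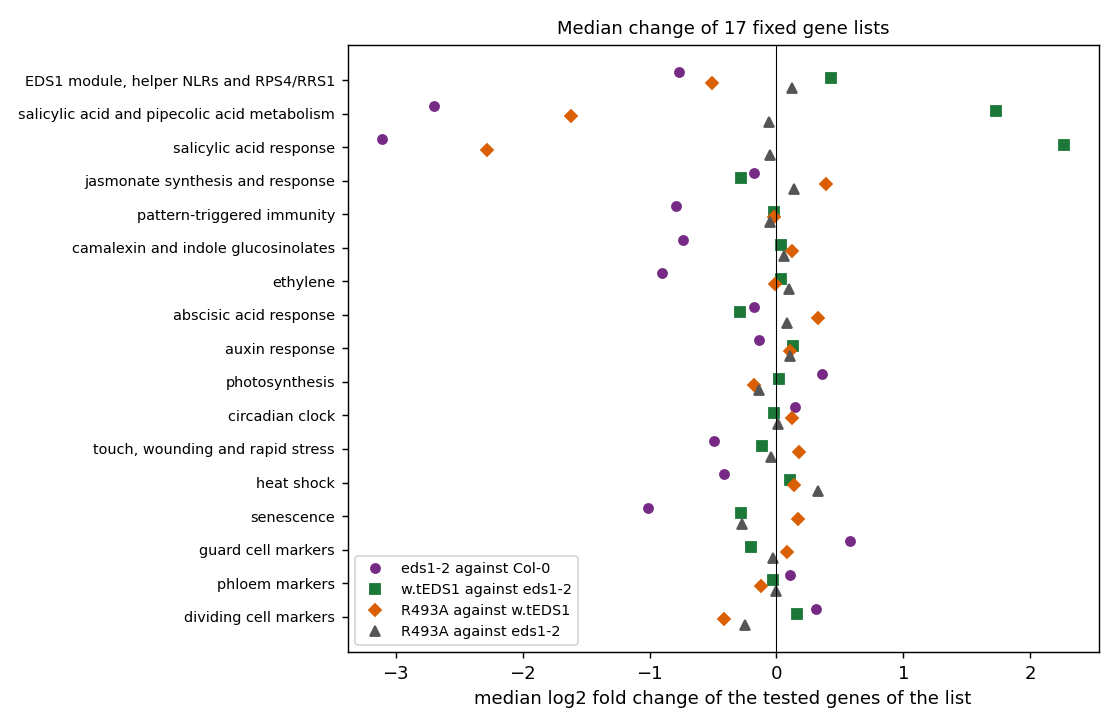
Median log2 fold change of the tested genes of 17 gene lists in 4 comparisons, each with its own marker. The salicylic acid response list lies at −3.11 in eds1-2 against Col-0, at 2.27 in w.tEDS1 against eds1-2, at −2.28 in R493A against w.tEDS1 and at −0.05 in R493A against eds1-2.

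The w.tEDS1 and R493A lines were also set against Col-0, to ask how far each stood from the wild type. In w.tEDS1 no named gene of the salicylic acid pathway was called, with ICS1 at −1.25 (adjusted p = 0.324), PAD4 at −1.12 (0.331), FMO1 at −2.27 (0.156), PR1 at 0.02 (0.994) and EDS1B at −2.31 (0.108). MYC2 (−0.21) and VSP2 (0.16) did not pass either. EDS1 was higher in w.tEDS1 than in Col-0 (1.76, SE 0.37, adjusted p = 0.0498; edgeR, n = 3). WRKY6, a senescence-associated transcription factor gene, fell from 182 ± 49.9 to 77.5 ± 7.79 CPM (−1.23, adjusted p = 0.0204), the glycosyltransferase gene AT3G46690 fell (−3.80, adjusted p = 0.0203) and RBCS1B was higher (0.76, adjusted p = 0.0258). The chromosome 3 genes differed again, with 0 counts of AT3G44430, 1 count each of CRK4, AT3G47680 and AT3G43740, and FAR8 (6.24), SADHU3-2 (6.12), AT3G45440 (4.95) and AT3G47580 (1.96) higher, and 1034 counts of AT3G44070 against 2. Without Col-0 replicate 2 the values were −0.29 for FMO1, 0.66 for ICS1 and 0.60 for PAD4, and Col-0 had no SADHU3-2 count. Without w.tEDS1 replicate 3 PR1 was −4.16.

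Here 95 genes were higher and 109 lower, of which 109 changed by at least 1 on the log2 scale. All 25 photosynthesis genes had positive values, with 7 called when adjusted over the list alone (median 0.40, camera adjusted p = 5.43e-09, adjusted p = 0.478 with an estimated correlation), and 7 of 9 senescence genes were called lower when adjusted over the list alone (median −1.23, camera adjusted p = 3.30e-05, adjusted p = 0.478 with an estimated correlation). Camera also placed lower the lists for jasmonate (−0.50), pattern-triggered immunity (−0.64), camalexin (−0.66), ethylene (−0.82) and salicylic acid metabolism (−1.02), with adjusted p from 3.30e-05 to 0.0144, and guard cells higher (0.37, adjusted p = 0.0444). With an estimated correlation these 6 had adjusted p = 0.478 or 0.573. Fry called no list between w.tEDS1 and Col-0. Without Col-0 replicate 3 the count was 2701, including all 204. Without Col-0 replicate 1 or 2 or w.tEDS1 replicate 1 or 3 it was 47, 88, 56 and 38. EDS1, WRKY6, AT3G46690 and RBCS1B were each lost without 4 or more of the 6 libraries in turn, Col-0 replicate 1 and w.tEDS1 replicates 1 and 3 among them (adjusted p up to 0.199 over the settings without the lane). CRK4 was lost without any w.tEDS1 library (adjusted p up to 0.0839), and SADHU3-2 in the 6 libraries alone (0.0555). The lane in the model left 26 genes called and lane 7 alone 19, with Col-0 replicate 3 alone for Col-0, and 9 and 10 of 14 named genes kept their calls, each on chromosome 3 (adjusted p of the others up to 0.552).

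In R493A against Col-0, WRKY70 (−3.85, SE 0.35, adjusted p = 0.000211), WRKY54 (−3.64, adjusted p = 0.000501), WRKY51 (−6.31, adjusted p = 0.000733) and SARD1 (−3.92, adjusted p = 0.00113) fell, and so did PBS3 (−4.19, adjusted p = 0.00739), UGT76B1 (−2.56, adjusted p = 0.00756), ICS1 (−3.92, adjusted p = 0.0389) and FMO1 (−4.93, adjusted p = 0.0391) by edgeR. PAD4 missed the threshold (−3.22, adjusted p = 0.0502), as did PR1 (−4.30, adjusted p = 0.267), MYC2 (0.27) and VSP2 (1.17). The helper receptor genes NRG1.2 (−1.84, adjusted p = 0.0128) and ADR1-L2 (−1, adjusted p = 0.0257), EDS1B (−4.73, adjusted p = 0.0212), CYP81F2 (−2.18, adjusted p = 0.0308), MYB51 (−2.32, adjusted p = 0.0413), SOBIR1 (−1.02, adjusted p = 0.0155) and WRKY6 (−1.16, adjusted p = 0.0189) were lower. RVE1 (1.22, adjusted p = 0.0484) and RBCS1B (0.72, adjusted p = 0.0232) were higher. On chromosome 3, HR4 (−10.56) was lower and FAR8 (6.79), AT3G45440 (4.87) and SADHU3-2 (6.34) higher, with 0 counts of AT3G43740, AT3G44430 and AT3G47680, and AT5G24240 (6.39) and MAF5 (2.82, adjusted p = 0.00867) were higher as against w.tEDS1.

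Against Col-0, 50 genes were higher and 283 lower in R493A. Of the 13 salicylic acid metabolism genes 9 fell, 12 when adjusted over the list alone (median −2.56, camera adjusted p = 1.93e-10, adjusted p = 0.189 with an estimated correlation), and of the 21 response genes 13 fell, 18 when adjusted over the list alone (median −3.06, camera adjusted p = 1.03e-16, adjusted p = 0.189 with an estimated correlation). The EDS1 module (−0.79), pattern-triggered immunity (−0.82), camalexin (−0.69), ethylene (−0.59) and senescence (−1.26) lists were lower, and photosynthesis (0.26) and guard cells (0.44) higher, with camera adjusted p from 3.15e-06 to 0.0124. With an estimated correlation these 7 had adjusted p = 0.268 to 0.423. Fry called only both salicylic acid lists (adjusted p = 0.00743 for each) and the senescence list (adjusted p = 0.0391), as lower. Without Col-0 replicate 3 the count was 2367, including all 333. Without Col-0 replicate 1 or 2 it was 129 and 146, and without R493A replicate 1, 2 or 3 it was 130, 87 and 83. WRKY70, WRKY54, WRKY51, SARD1 and UGT76B1 stayed called without any single library and in the 10 other settings without the lane (adjusted p up to 0.0431). PBS3 was lost without R493A replicate 2 or 3 (up to 0.0979 over the settings without the lane), NRG1.2 without those or Col-0 replicate 1 (up to 0.113), ICS1 without any R493A library (up to 0.205) and MAF5 without R493A replicate 3 (0.0501). FMO1, EDS1B, ADR1-L2, CYP81F2, SOBIR1, RVE1 and RBCS1B were lost without any library but Col-0 replicate 3, and MYB51 and WRKY6 without 4 of the 6 libraries in turn (up to 0.209). Without Col-0 replicate 2 the values moved to −2.01 for ICS1, −1.49 for PAD4, −2.95 for FMO1, −1.41 for MYB51 and −1.45 for CYP81F2, and Col-0 had no SADHU3-2 count. PR1 moved to −1.73 without Col-0 replicate 1. Without R493A replicate 2 no PR1 count was left in R493A, so the size of its fold is unknown. The lane in the model left 19 genes called and lane 7 alone 15, again with Col-0 replicate 3 alone. Of 29 named genes 9 kept their calls in each, AT1G57650, AT5G24240 and 7 on chromosome 3 (adjusted p of the others up to 0.985), and all 29 kept their direction. WRKY70 lay at −2.94 in both (SE 0.42, adjusted p = 0.110 and SE 0.52, adjusted p = 0.577).

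The eds1-2 effect against Col-0 and the R493A effect against w.tEDS1 share no library, so they were compared gene by gene. Among the genes lower in both were WRKY70, WRKY54, WRKY51, SARD1, NRG1.2 and RLP34. Of the 39 genes lower in R493A than in w.tEDS1, 20 were also lower in eds1-2 than in Col-0, against 0.561 for independent lists, and 30 of the 39 had negative values there. Only 3 genes were higher in R493A than in w.tEDS1, and none of them was called higher in eds1-2, against 0.0181 expected. Outside the window around EDS1, 156 of the 196 genes lower in eds1-2 had negative values in R493A against w.tEDS1, but 17 of the 101 genes higher in eds1-2 had positive ones. Across all 18770 genes the log2 fold changes correlated by Pearson's coefficient at 0.226 (jackknife SE 0.145) and by Spearman's at −0.154, so the sign differed between the coefficients, and genes are not independent replicates. Without the filter on low counts Pearson's coefficient was 0.0801.

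The size of these effects differed for 30 genes in the test of the difference, 14 with a positive and 16 with a negative difference, and 15 of them lie within 2 Mb of EDS1. Among them were HR4, FAR8, AT3G44070, AT3G45440, AT3G47580, GSA2 and SADHU3-2 on chromosome 3, which differed between Col-0 and the other lines. Away from that region AT4G16870 differed by −5.32 (SE 0.41, adjusted p = 0.000158) and MAF5 by 4.47 (adjusted p = 0.0190), and AT1G57650 and AT3G05410 were called too. Without Col-0 replicate 3 the count was 440, including all 30. Without Col-0 replicate 1 or 2 it was 13 and 20, without w.tEDS1 replicate 1, 2 or 3 it was 11, 17 and 12, without eds1-2 replicate 1, 2 or 3 it was 15, 14 and 17, and without R493A replicate 1, 2 or 3 it was 15, 14 and 13. Once the lane was in the model it was 6, with 5 of the 30, and in lane 7 alone 1, with 0 of them, and Col-0 rested on replicate 3 alone.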

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

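All counts of other splits of the libraries, the fits by lane and all tests of explanations in this part were chosen after the results were seen, and the test of the difference between the EDS1 effects was planned.

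The effect of R493A against w.tEDS1 differed from the effect of eds1-2 against Col-0 for 30 genes. Of 100 splits of the libraries, 1, the real one, gave as many, and the highest of the others gave 21. The splits mix genotypes, so they ask whether the genotypes differ at all and not whether the effects are equal. Of the 30 genes, 15 lie within 2 Mb of EDS1, where Col-0 differed from the other lines. Col-0 replicates 1 and 2 also stood apart, so the libraries may not be exchangeable. The splits therefore cannot exclude chance for the count of 30 as a difference of the effects. With the replicate number as a block the count was 13 and with the lane in the model, where Col-0 rests on replicate 3 alone, 6, and no splits were drawn within blocks or lanes. In R493A replicate 2, 19.65% of the column total was reads that mapped to more than 1 place, above the highest Col-0 library at 14.33%. The means of that share were 14.4% in R493A and 11% in Col-0 (exact permutation test, two-sided p = 0.5), and 3 against 3 libraries cannot give a p under 0.1. Reads outside annotated genes made up 2.609% of that library, above the highest Col-0 library at 2.439%. Single outlying libraries were not tested for in these groups of 3.

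Genes within 2 Mb of EDS1 differed between eds1-2 and Col-0, 84 of them besides EDS1 and EDS1B. Lack of EDS1 function is argued against as the whole cause, since w.tEDS1 reverted a median of 4.07% of the change (quartiles −6.73 and 15.9%). The 297 genes called outside the window were reverted by a median of 19.8% (quartiles 0 and 62.4%), and the 196 lower ones among them by 42.3% (14.0 and 76.6%). Loss of reads from a diverged haplotype cannot have made the genes that were higher in eds1-2, which were 14.3% of the 84 (12 genes, with a lower bound of 7.61% from the exact binomial interval). Other effects of mapping on these higher genes were not tested. For the 72 lower genes, lost reads and lower transcript levels cannot be told apart without the sequence of the lines. A candidate explanation is a chromosome 3 segment of another accession kept in all 3 lines, which was not tested.

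The 13 genes that were higher in w.tEDS1 than in eds1-2, besides EDS1, were low in R493A. A response in proportion to the measured EDS1 counts is argued against as the whole cause, since these genes lay at a median of −3.85 against Col-0 (quartiles −4.33 and −2.70), while EDS1 itself lay between −1.62 and 0.06. Against eds1-2 they lay at −0.15 (−0.38 and 0.19) and EDS1 between 1.72 and 3.57. Against w.tEDS1 alone such a response would not be excluded, with these genes at −3.33 (−4.70 and −3.25) and EDS1 between −3.42 and −1.66. EDS1 lies in the block where reads of another haplotype may be lost, and it may share reads with EDS1B. The argument therefore holds only as far as EDS1 counts give the EDS1 level. The sequencing run is argued against as the whole cause, since in the main run alone the median of the 13 genes against w.tEDS1 was −3.50 (quartiles −4.55 and −3.18). So is the sequencing lane, since with the lane in the model their median was −3.35 (quartiles −4.71 and −3.15), against −3.33 in the model without it, though R493A rested on replicates 1 and 3 there. The calls of all 13 ended there (lowest adjusted p = 0.130), where the median SE was 0.57 against 0.47 and 4 residual degrees of freedom were left. The design gives the R493A exchange as the biological explanation, and it remains open as a hypothesis. A threshold in EDS1 level, an altered amount of EDS1 protein and other differences of the R493A line also remain open and may contribute.

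Between R493A and w.tEDS1, 28 genes were called that had not been called between w.tEDS1 and eds1-2. Changes at single loci of the R493A line, such as an insertion, may explain part of them. The test used random sets of tested genes, so it cannot tell such changes from shared regulation of neighbours. Of the 28 genes, 5 lay within 50 kb of another gene of the set, against a median of 0 and a 95th percentile of 2 in 10000 random sets (permutation p = 0.0057). These were AT1G54410 (−7.27) and AT1G54420 (no count in w.tEDS1, at least 69-fold higher), side by side on chromosome 1, and AT4G16870 (−4.89), AT4G16892 (−1.89) and AT4G16910 (−2.41) on chromosome 4, around RPP4 and SNC1, which were not called (−0.55 and −0.33). Among the other 23 genes, NAC004, AT2G15042, RLP34, SIB1, WRKY50 and NRG1.2 were also called lower in eds1-2 than in Col-0. These need not be particular to the R493A line, although they were not called between w.tEDS1 and eds1-2. The cause remains open for the 23 genes, and an effect of the variant on them is untested, since the labels do not say how many independent lines carry it.

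For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05, so only the real value and the highest of the other splits are given. For eds1-2 against Col-0, 2 of the 10 splits gave at least the real count of 383 genes. The other one, Col-0 replicates 1 and 2 with eds1-2 replicate 3, called 1000, which points to a structure of the samples. Those Col-0 libraries were the ones sequenced in lane 6, and they lay at −62.9 and −92.6 on the first principal component, with Col-0 replicate 3 at −0.307. Lane 6 and a difference between these plants cannot be told apart, since lane 6 held no other library, and this bears on all counts and folds against Col-0. With the lane in the model 13 genes were called and in lane 7 alone 10, where Col-0 rests on replicate 3 in both. In the other comparisons 1 split, the real one, was as large: 14 against 0 for w.tEDS1 and eds1-2, 42 against 0 for R493A and w.tEDS1, 7 against 0 for R493A and eds1-2, 204 against 1 for w.tEDS1 and Col-0 and 333 against 0 for R493A and Col-0. Of the 4 splits that part all 3 R493A and w.tEDS1 pairs, the others called 0 at most. In the window around EDS1 it was 86 against 37 for eds1-2, 68 against 0 for w.tEDS1 and 81 against 0 for R493A, each against Col-0.

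The counts of gene lists called by camera were not exceptional among the splits. For eds1-2 against Col-0, 5 of 10 splits called at least the real 9 lists, up to 13. For w.tEDS1 against eds1-2, 8 splits called at least 6, up to 10, and for R493A against w.tEDS1, 5 called at least 6, up to 8. For R493A against eds1-2, 10 called at least 1, up to 6. For w.tEDS1 against Col-0, 5 called at least 8, up to 13, and for R493A against Col-0, 6 called at least 9, up to 12. The correlation of 0.226 between the effects was reached in size by 2 of the 10 splits of R493A and w.tEDS1, the real one and another at −0.334, and splits of eds1-2 and Col-0 gave values down to −0.367.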

How the results depend on the processing

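The fits with quality weights, with 1 surrogate variable, with the replicate block within 6 libraries, with the lane as a covariate and in lane 7 alone, and the leaving out of libraries for the difference of effects and for the correlation, were chosen after the data were seen. Among called named genes, no direction was reversed: 906 values under other settings stayed called and 343 did not, and with a library left out 399 stayed called and 219 did not. Uncalled genes kept side and direction 385 and 199 times and became called 21 and 6 times. Of the lists' calls 79 were kept and 38 lost. The cause was not tested unless named.

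Counts of called genes are given for eds1-2 against Col-0, w.tEDS1 against eds1-2, R493A against w.tEDS1, R493A against eds1-2, w.tEDS1 against Col-0, R493A against Col-0 and the difference of effects, in that order and only where they moved by over 1.5 times. DESeq2 called 1843, 84, 155, 31, 1749, 1456 and 527. Limma-voom called 223, 6 and 23, then 185 and 50 in the last 2. With the replicate number as a replicate block the counts were 132, 6, 15, 4, 87, 159 and 13, and the paired fit within 6 libraries called 186 for R493A against w.tEDS1. Same-numbered libraries correlated at −0.509 to 0.381, 4 of 18 pairs over 0.1, and 1 library correlated best with its own number. With the run as a covariate the counts were 136 and 2, then 571, 181 and 118 in the last 3. In the main run alone, with fewer libraries, they were 56, 0, 8 and 4, then 71 and 13 in the last 2. With the lane as a covariate, which leaves 4 residual degrees of freedom, the counts were 13, 0, 5, 3, 26, 19 and 6, and in lane 7 alone, which leaves 2, they were 10, 0, 2, 1, 19, 15 and 1. In both Col-0 rests on replicate 3 alone, and in lane 7 eds1-2 and R493A have 1 library each, so lost calls and changed signs there come with fewer libraries. Quality weights gave 2894, 92, 123, 35, 2879, 1776 and 1455, and 1 surrogate variable 157, 22, 83 and 15 in the first 4. Fitted on 6 libraries alone, with fewer residual degrees of freedom, the counts were 50, 27 and 75, then 39 and 80 against Col-0. Without a filter R493A against eds1-2 gave 13 and the correlation was 0.0801. A minimum change of 1 left 109 for w.tEDS1 against Col-0, and without the window the difference of effects held 15. With an estimated correlation 2 of 39 list calls passed.

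With 1 library left out the counts ranged from 57 to 3338, 1 to 17, 4 to 35, 3 to 5, 38 to 2701, 83 to 2367 and 11 to 440, the highest against Col-0 and for the difference without Col-0 replicate 3. Uncalled genes that changed sign, as log2 fold changes, were MYC2 in eds1-2 against Col-0, which was 0.00 and became 0.06 with limma-voom, 0.03 with the replicate block, 0.16 with quality weights, 0.25 with a surrogate variable, 0.01 in 6 libraries alone, 0.02 with the lane as a covariate and 0.00 in lane 7 alone. In R493A against eds1-2 FMO1 became 0.31 and PR1 −4.07 in the main run alone, and PAD4 −0.05 with a surrogate variable. In w.tEDS1 against Col-0 a surrogate variable gave FMO1 0.09, ICS1 0.44, MYC2 0.03 and PAD4 0.31, quality weights gave MYC2 0.05 and PR1 −0.99, the replicate block gave PR1 −0.98 and no filter gave PR1 0.00. With the lane as a covariate PR1 became 0.90 in eds1-2 against Col-0, MYC2 0.02 in w.tEDS1 against eds1-2 and FMO1 0.27, PR1 −4.03 and VSP2 −0.02 in R493A against eds1-2. EDS1B became 0.70, FMO1 0.94, ICS1 1.42, MYC2 0.05 and PAD4 1.08 in w.tEDS1 against Col-0, and EDS1 0.30 in R493A against Col-0. In lane 7 alone MYC2 became 0.05 in w.tEDS1 against eds1-2 and FMO1 0.52, ICS1 0.21 and VSP2 −0.46 in R493A against eds1-2. EDS1B became 0.69, FMO1 0.93, ICS1 1.42, MYC2 0.05 and PAD4 1.09 in w.tEDS1 against Col-0, and EDS1 0.42 in R493A against Col-0, where neither library had a PR1 count. With 1 library left out, MYC2 in eds1-2 against Col-0 ranged from −0.19 to 0.38. In R493A against eds1-2 EDS1B ranged from −0.05 to 1.00, FMO1 from −0.81 to 0.14, PAD4 from −0.01 to 0.31, PR1 from −3.49 to 6.33 and VSP2 from −0.16 to 0.48. In w.tEDS1 against Col-0 ICS1 ranged from −1.76 to 0.66, MYC2 from −0.41 to 0.16, PAD4 from −1.60 to 0.60, PR1 from −4.16 to 2.58 and VSP2 from −0.05 to 0.29. Depth limits the genes with 0 to 3 counts in a group, whose folds are bounds or unknown.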

Other observations

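The genes in this part were chosen after their values were seen, and no explanation was tested for them here.

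FLC (AT5G10140), the central repressor of flowering, had 1 count in the 3 R493A libraries and lay at 0.922 ± 0.490 CPM in w.tEDS1 (SD, n = 3). FES1 (AT2G33835), which promotes FLC expression, lay at 1.04 ± 1.18 CPM in R493A and at 10.7 ± 0.780 in w.tEDS1 (log2 fold change −3.34, SE 0.56, adjusted p = 0.0405; edgeR). MAF5, of the same family as FLC, was 4.09 higher. AGL62, a MADS-box gene of endosperm development, lay at 0.0624 ± 0.0255 CPM in R493A and 0.794 ± 0.280 in w.tEDS1 (adjusted p = 0.0267). SIB1 (AT3G56710), which encodes a sigma factor-binding protein, lay at 34.4 ± 14.9 CPM in Col-0, 25.9 ± 13.0 in w.tEDS1, 4.94 ± 0.371 in eds1-2 and 4.27 ± 1.35 in R493A, lower in R493A than in w.tEDS1 (−2.60, adjusted p = 0.0311). WRKY50 (−3.52, adjusted p = 0.0410), NAC004 (−3.69, adjusted p = 0.0256) and RLP38 (−2.70, adjusted p = 0.0398) were lower in the same comparison.

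The nitrilase genes NIT1 and NIT3, which lie side by side on chromosome 3, had higher mean levels in Col-0 than in the other 3 lines. The p-values given for them are of the difference of effects and do not test Col-0 against each line. NIT1 (AT3G44310) lay at 1806 ± 436 CPM in Col-0 and at 589 ± 22.0 in w.tEDS1, 645 ± 42.4 in eds1-2 and 675 ± 43.8 in R493A (difference of effects 1.68, SE 0.23, adjusted p = 0.0167). NIT3 (AT3G44320) lay at 27.1 ± 8.95 CPM in Col-0 and between 7.49 and 11.5 in the others (difference of effects 2.05, adjusted p = 0.0189). ERD5 (AT3G30775), a proline dehydrogenase gene on the same chromosome, lay at 101 ± 9.29 CPM in Col-0 and between 38.1 and 39.7 in the others (1.32, adjusted p = 0.0295). The pseudogene AT5G20750 on chromosome 5 had no count in Col-0 and lay at 7.37 ± 0.280 CPM in w.tEDS1, 6.68 ± 1.11 in eds1-2 and 4.2 ± 0.417 in R493A. AT1G54410 kept 18.6 CPM in R493A replicate 1 and less than 1 CPM in the other 2 R493A libraries, against 1010 ± 144 CPM in eds1-2.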
